A study of Mus musculus with 2 samples.

How the data were processed

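Single-cell libraries of 2 groups were used, control siRNA and Chd4 siRNA, with 1 library each. Per the labels, cells were transfected with 75 pmol siRNA and 2 µL Lipofectamine on plastic for 24 h, and equal numbers of cells of 3 biological replicates were combined per group before droplet capture with 10x Genomics v2 chemistry. The deposited matrices hold raw UMI counts per gene and cell, per the file headers and the values, which are whole numbers. Cell Ranger 2.1.0, Seurat and the mm10 build are named in the submitters' processing notes, with no roles given. How cells were called or filtered before deposit is not given in the sources used here.

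The gene list held here names 26893 of the 27998 matrix rows. The other 1105 rows, which held 12.1% of UMIs in the control library and 12.6% in the Chd4 siRNA library, stayed out of totals and ratios. Genes of the last part of chromosome 18, of chromosome 19 and of the mitochondrial genome were therefore not analysed here, among them Gfra1, Dmrt1 and the mitochondrially encoded genes, and no filter on mitochondrial UMIs was applied. Each matrix as held ends inside its last cell, and that cell was left out. This left 816 complete cells in the control library and 860 in the Chd4 siRNA library. Cells with at least 1000 UMIs were kept, which removed 0 and 2 cells.

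Cells were clustered with scanpy 1.11.5. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5 (leidenalg 0.10.2) were used. A cluster took the name of the cell type with the highest share of its markers met, if at least 3 were met. The markers were fixed before the data were examined. A marker was met when found in at least 10% of the cluster's cells and at least 2-fold above the cluster where it was lowest. The name was withheld when the cluster's 10 leading genes held more markers of another type than of its own. It was also withheld from clusters of low depth with no marker of their own type among those genes. All 3 germ cell-like clusters were joined in 1 class. Scrublet, at an expected rate of 1%, called 20 cells (2.45%) of the control library and 6 (0.70%) of the Chd4 siRNA library doublets. These cells were kept, and removing them was an alternative.

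UMIs were summed per library over the germ cell-like class (11587651 and 12221480 UMIs) and the feeder fibroblast-like class (3173289 and 3656226 UMIs) and divided by the total to give CPM. A log2 ratio is Chd4 siRNA over control siRNA. Its interval is the exact conditional binomial (Clopper-Pearson) 95% interval, sums have exact Poisson intervals, and shares have Clopper-Pearson intervals. All of these cover counting error only, since cells are not replicates. No p-value was computed. The depth fixes the precision: the Chd4 ratio is known to within a few percent, whereas genes near 200 UMIs have intervals wider than 0.5 on the log2 scale.

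The named genes were fixed by rule before the data were examined: among genes with at least 200 UMIs in the germ cell-like class of both libraries together, the 12 highest and the 12 lowest by the interval bound nearest to no difference, Chd4, and up to 4 members per gene list by the same bound. Others named in the text were taken to describe the range of a list. The 21 gene lists were also fixed beforehand, and the list of mitochondrially encoded genes could not be measured. A list's median was taken over members with at least 20 UMIs, with an interval from 1000 Poisson redraws and its percentile among 10000 random lists of the same size drawn from 20 bins of expression.

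To compare shares and phases, each cell was thinned to 9000 UMIs, and shallower cells were left out, 62 and 66 of the germ cell-like class and 3 and 6 of the feeder class. Phases were called with scanpy's cell cycle scores on the S phase and G2/M phase lists. Gene positions, transcript lengths and 3′ UTRs came from the GENCODE annotation of the same mouse assembly as mm10.

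The steps were tested on simulated counts for this comparison, over 26893 genes with 200 changed by known amounts. These were Poisson counts around the summed UMIs of all cells, not of the germ cell-like class. Since the intervals assume the same counting model, the test checks the code and says nothing on spread between cells or replicates. All 24 genes that the rule then named were truly changed. The intervals covered the true ratio for 88% to 98% of the 50 genes at each changed size, and 4 of 100 unchanged lists lay outside the 2.5 to 97.5 percentiles. Alternatives were TMM factors (edgeR 4.0.16) and DESeq2 size factors (1.42.0), used for scaling only, in R 4.3.3; means of per-cell CPM; all deposited cells; at least 5000 UMIs per cell; thinned cells; doublets removed; other minimum counts; means of list members; cells of single phases; totals without ribosomal protein genes; other clustering resolutions; and unthinned cells. Germ cell-like clusters given the UMI shares of the control library in both libraries, single clusters for 2 lists with members among the leading genes of a cluster, cells with at most 20% of UMIs in unnamed rows, and, for feeder cell lists, cells with under 150 CPM of germ cell markers or the germ cell profile subtracted at the share those markers give, were alternatives chosen after seeing the data.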

Results

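The data were single-cell transcriptomes of mouse undifferentiated spermatogonia in primary culture, the population that holds the stem cells of the male germline. The cells came from adult C57BL/6 testes by selection for the surface protein THY1 and grew on mitomycin-treated SNL76/7 fibroblasts, a feeder layer, with the growth factors GDNF and bFGF. They received either a non-targeting control siRNA or an siRNA against Chd4, the ATPase of the NuRD chromatin remodelling complex, for 24 h. Cells of 3 biological replicates were combined before loading, so each group was 1 library and the replicates could not be told apart. The control library held 816 complete cells with 14826257 UMIs in named genes and a median of 15625.5 UMIs and 4075 genes per cell. The Chd4 siRNA library held 860 complete cells with 15920307 UMIs and a median of 16136.5 UMIs and 4152 genes per cell, and 858 of them were kept. No difference below has a replicate check and none was tested across replicates. Each interval is a 95% interval for counting error only, and the words higher and lower compare these 2 libraries.

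The first question was whether the siRNA lowered its target. Chd4 was lower by more than counting error in the germ cell-like class and in the feeder fibroblast-like class. In germ cell-like cells the library totals were 6217 Chd4 UMIs under control siRNA and 3098 under Chd4 siRNA, or 536.5 CPM (523 to 550) and 253.5 CPM (245 to 263). The ratio was 0.472 (0.452 to 0.493), a log2 ratio of −1.08 (−1.14 to −1.02). The feeder fibroblast-like cells had 493 and 192 Chd4 UMIs, or 155.4 and 52.5 CPM, and a log2 ratio of −1.56 (−1.81 to −1.32). Chd4 (ENSMUSG00000063870) lies on chromosome 6 at 125095981 to 125130591 of the mm10 assembly.

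At equal depth, 97.4% of germ cell-like cells in the control library carried a Chd4 UMI, against 81.2% in the Chd4 siRNA library, a difference of −16.3 percentage points (−19.6 to −13.1). Without thinning the shares were 98.5% and 89.4%. The thinned feeder fibroblast-like cells had a Chd4 UMI in 73.7% and 33.7%. No class in the data is known to lack Chd4, so no background share was set for it.

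**Figure D1:**
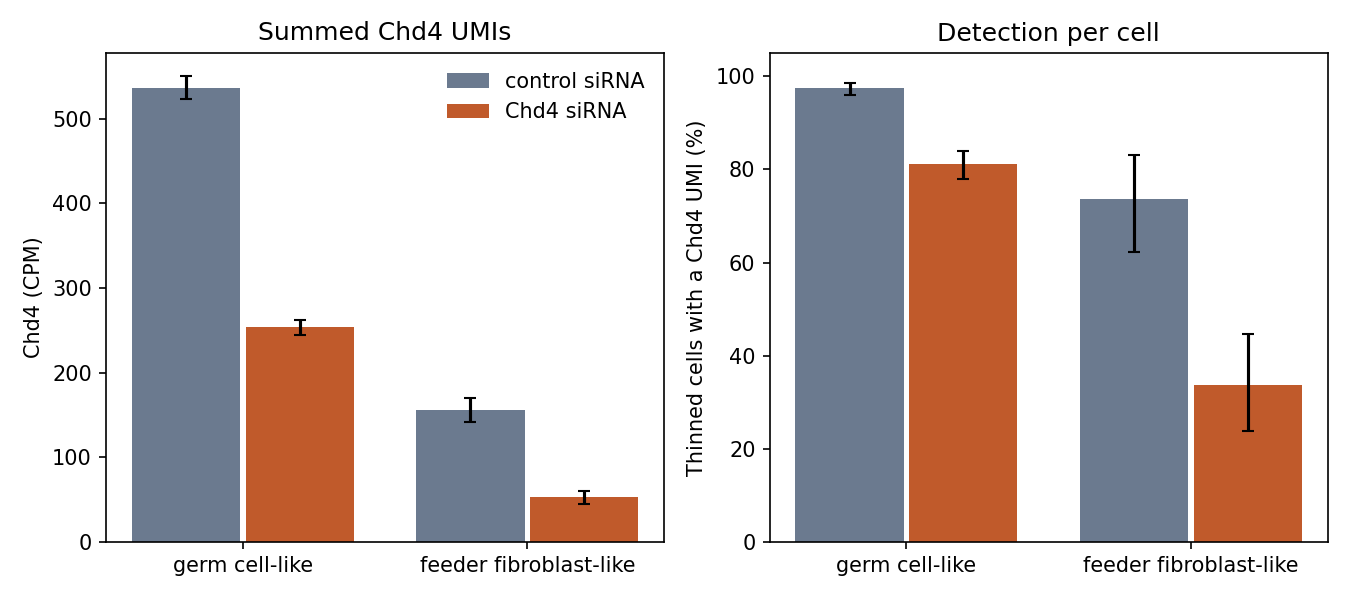
Left, Chd4 level in CPM of the summed UMIs of each class, with exact Poisson 95% intervals; right, percent of cells thinned to 9000 UMIs with at least 1 Chd4 UMI, with exact binomial 95% intervals. Chd4 went from 536.5 to 253.5 CPM in germ cell-like cells and from 155.4 to 52.5 CPM in feeder fibroblast-like cells.

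The next question was whether the makeup of the cultures differed. Germ cell-like cells, which carried all 12 measured germ cell markers such as Ddx4, Dazl and Zbtb16, were 727 of 816 cells in the control library, or 89.1% (86.8 to 91.1). They were 761 of 858 cells in the Chd4 siRNA library, or 88.7% (86.4 to 90.7). Feeder fibroblast-like cells, with 17 of 18 fibroblast markers such as Col1a1, Col3a1 and Fn1, made up 9.68% (7.74 to 11.9) and 10.7% (8.73 to 12.99). Both of these class differences lay within counting error. The germ cell-like class joined 3 clusters, led by Nanos2, by Esco2 and by Tmc3, the last with Dhcr7 and the endoplasmic reticulum stress gene Herpud1 among its 10 leading genes. In that order the clusters held 330, 218 and 179 cells of the control library and 314, 211 and 236 of the Chd4 siRNA library. These sizes cannot be read apart from the gene results, since several of the leading genes differed between the libraries. The gene results were therefore also computed with the clusters at equal shares in both. The remaining 10 and 5 cells formed a cluster led by Ass1 and S100a4 that stayed unnamed. At resolution 1.0, 3 and 12 cells of low depth formed a further unnamed cluster, with medians of 45.2% and 44.3% of UMIs in unnamed rows. The main resolution gave no such cluster. There, 719 of the 727 and 740 of the 761 germ cell-like cells had at most 20% of UMIs in such rows.

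The main comparison asked which genes of the germ cell-like cells differed between Chd4 and control siRNA. Among 8247 genes with at least 200 UMIs, 97.7% had a log2 ratio within 0.5 of 0, and the median was 0.05. Of the 12 lowest, ranked by the interval bound nearest to no difference, ratios ran from 0.363 to 0.508. Among the 12 highest they ran from 1.49 to 2.12.

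The lowest log2 ratio among these belonged to Yrdc, an enzyme needed for a universal tRNA modification, with 66.5 CPM under control and 24.1 CPM under Chd4 siRNA (log2 −1.46, −1.66 to −1.27). Hist1h2ap, a histone H2A gene, had a log2 ratio of −1.23 (−1.42 to −1.06). Klf2, a Krüppel-like transcription factor, stood at −1.12 (−1.38 to −0.87), Gatad1, a GATA zinc finger protein, at −1.06, and Taf10, a subunit of TFIID, at −1.04. Bod1, a protein of chromosome biorientation, and Jund, an AP-1 transcription factor, were both at −1.03, and the RNA polymerase subunit gene Polr2l was at −0.98. Gm10076, Gm8186 and Gm10269 completed the 12 with −1.39, −1.16 and −1.03. These predicted genes are short loci annotated as a lincRNA and processed pseudogenes. Their counts can therefore be shared with other genes and are uncertain, as are those of the near-identical histone genes. In feeder fibroblast-like cells the predicted genes stood at −1.28, −1.65 and −1.23. Short mRNAs as a group were also lower in both classes, as described at the end. Whether this bears on these short loci was not tested.

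The highest log2 ratios belonged to Pdlim4, a PDZ and LIM domain protein, at 1.08 (0.75 to 1.42), from 9.32 to 19.7 CPM. Gprasp2 followed at 1.03 (0.61 to 1.47) and Mdk, the heparin-binding growth factor midkine, at 0.99 (0.65 to 1.33). Fndc4 was at 0.91, the small heat shock protein gene Hspb2 at 0.90, the circadian and stress-linked repressor Bhlhe40 at 0.85, and the receptor activity modifier Ramp2 at 0.84. Fbxo2 had 0.79, the phospholipid flippase gene Atp9a 0.69 and the octamer factor gene Pou2f2 0.67. Reep5, a protein that shapes the endoplasmic reticulum, had the most UMIs of these genes, 1172 and 1846, and a log2 ratio of 0.58 (0.47 to 0.69). Col1a1 was at 0.77, but it is a marker of the feeder class, and the summed fibroblast markers in germ cell-like cells stood at 709 and 787 CPM.

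The feeder fibroblast-like cells shared some of these differences: 10 of the 12 lower genes lay below the feeder median. These included the siRNA target Chd4 itself, and Yrdc, whose interval there included 0. Of the 12 higher genes, 7 had fewer than 20 UMIs there and could not be compared, and the other 5 lay above it, Reep5 and Atp9a with intervals that included 0. Taf10 had a log2 ratio of −1.28 (−1.44 to −1.13) there, Polr2l −0.99 (−1.17 to −0.81) and Hist1h2ap −1.70. Yrdc, in contrast, stood at −0.09 (−0.50 to 0.33), Bod1 at 0.11 (−0.27 to 0.51) and Jund at 0.26 (−0.01 to 0.53). Across 3856 genes with at least 200 UMIs in each class, the log2 ratios of the classes had a Pearson correlation of 0.39. Genes are not independent replicates, and both classes came from the same libraries, so effects shared by a whole library also enter this value. The choice of cells bore on which genes led: only 10 of the 24 were named when all cells were used.

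**Figure D2:**
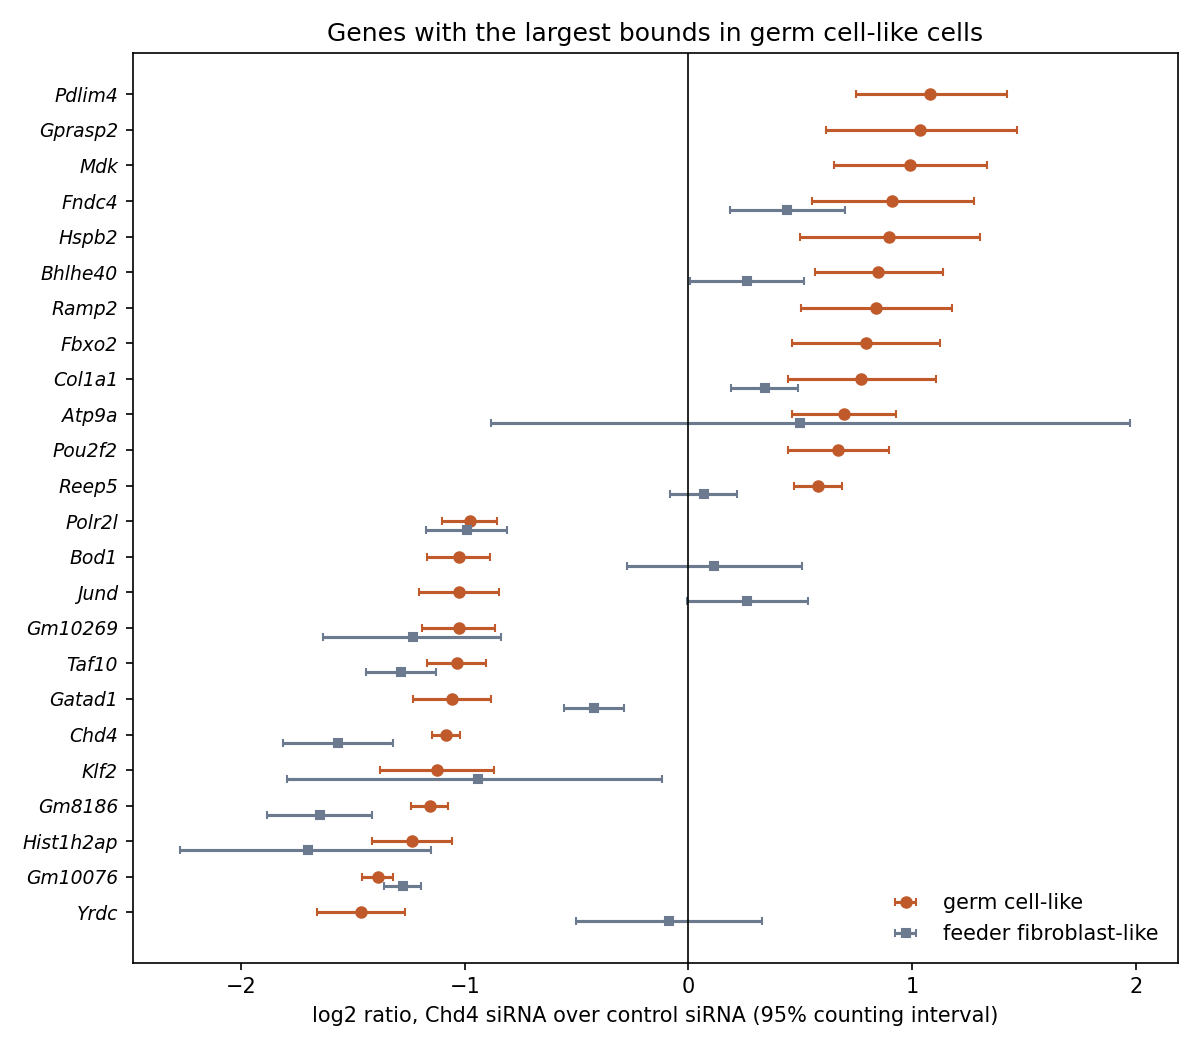
Log2 ratio of Chd4 siRNA over control siRNA for the 24 genes named by the rule, in germ cell-like cells (circles) and, with at least 20 UMIs, in feeder fibroblast-like cells (squares), with exact conditional 95% counting intervals. Yrdc, Bod1 and Jund were low in germ cell-like cells, at −1.46, −1.03 and −1.03, but not in feeder fibroblast-like cells.

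Genes of stem cell maintenance were considered next, since the study title concerns the stem cell pool. Self-renewal and GDNF-responsive genes had a median log2 ratio of −0.03 (−0.13 to 0.02), and 12 of 16 measured members lay below the median of all genes. That median was at the 5.58 percentile of random lists matched on expression. Pou3f1, a POU factor induced by GDNF, was at −0.27 (−0.40 to −0.13), Nanos2, an RNA-binding protein of the stem cell state, at −0.25 (−0.50 to −0.01), and Lhx1, a LIM homeobox factor, at −0.19 (−0.32 to −0.06). Etv5 and Ret, a target of GDNF signalling and its receptor, were at 0.01 and 0.05 with intervals that included 0, as was Id4 at −0.03 (−0.36 to 0.31).

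Core regulators of undifferentiated spermatogonia had a median of 0.02 (−0.15 to 0.10) over 11 members, at the 31.3 percentile. Within the list, members went both ways. Sall4, a zinc finger factor that binds NuRD, was at −0.30 (−0.48 to −0.13) and Foxc2 at −0.34 (−0.52 to −0.16). The pluripotency factor gene Pou5f1 was at 0.42 (0.28 to 0.57), Uchl1 at 0.09 (0.03 to 0.15) and Zbtb16, which encodes PLZF, at 0.05.

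In thinned germ cell-like cells the shares with a UMI differed by no more than counting error for these genes. Nanos2 was seen in 18.8% under control and 15.1% under Chd4 siRNA, Sall4 in 32.0% and 28.6%, and Zbtb16 in 56.4% and 56.8%. Without thinning, Sall4 was seen in 48.7% and 42.2%, a difference of −6.51 points (−11.6 to −1.36), and Nanos2 in 27.9% and 24.0%. At least 2 Sall4 UMIs were seen in 8.87% and 5.47% of thinned cells, a difference of −3.40 points (−6.29 to −0.57). In feeder fibroblast-like cells, which are not known to use these genes and had medians of 38655 and 39671.5 UMIs against 15299 and 15506 in germ cell-like cells, the thinned share for Sall4 was 5.26% and 1.16%. For Zbtb16 the feeder shares were 1.32% and 1.16%. Transcripts of Kit, Stra8 and Neurog3 were found in under 4% of thinned germ cell-like cells of either library, and Rarg was found in fewer of them than of feeder fibroblast-like cells.

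Progenitor genes had a median of 0.11 (−0.05 to 0.22) at the 81.6 percentile, with 5 of 8 members above the all-gene median. Genes of differentiating spermatogonia had a median of 0.16 (0.05 to 0.34) at the 91.9 percentile, with 6 of 8 members above it. Crabp1, which binds retinoic acid, was at 0.60 (0.41 to 0.80), Sohlh2, a helix-loop-helix factor of differentiation, at 0.35 (0.13 to 0.57) and Tex15 at 0.20 (0.12 to 0.28). Kit, with 17 and 13 UMIs, could not be compared at this depth.

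Meiotic genes had a median of 0.02, at the 36.9 percentile, with Sycp1 at 0.17 (0.07 to 0.27) and Tex101 at 0.15. Germline genome-defence genes, which restrain transposons and support germ cell RNA handling, had a median of 0.13 (0.07 to 0.17) at the 96.1 percentile, with 8 of 11 members above the all-gene median. Dazl was at 0.14, Mael at 0.15 and Ddx4 at 0.13, while Piwil2 was at −0.23 (−0.36 to −0.10).

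The other measured NuRD subunits did not share the low level of Chd4 as a group. Of the 15 list members 13 had a named row, and Mta2 and Mbd2 were not measured. The list, Chd4 included, had a median of 0.10 (0.01 to 0.14) and a mean of −0.01. The mean was lower because Chd4 and its paralog Chd3, at −0.38 (−0.54 to −0.23), lay far below the rest. Chd5 was at 0.55 (0.17 to 0.93), from 98 and 151 UMIs, Gatad2b at 0.21 and Gatad2a at −0.14. Other CHD and SWI/SNF remodellers had a median of 0.07 at the 68.1 percentile, with Smarcc1 at 0.21 and Smarca5 at −0.17.

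Integrated stress and unfolded protein response genes had a median of 0.20 (0.09 to 0.27), at the 99.8 percentile, with 9 of 14 members above the all-gene median. The transcription factor gene Atf3 was at 0.72 (0.23 to 1.22), Nupr1 at 0.74, Trib3 at 0.60, asparagine synthetase Asns at 0.37 and Ddit3, which encodes CHOP, at 0.25 (0.13 to 0.37). With members of at least 200 UMIs the median was 0.07. Within single clusters it was 0.31 (0.09 to 0.45) in the cluster led by Esco2, but 0.030 (−0.11 to 0.16) in that led by Nanos2 and 0.036 (−0.06 to 0.19) in that led by Tmc3, at the 57.8 and 45.2 percentiles. With equal cluster shares in both libraries it was 0.11. Heat shock and dissociation genes had a median of 0.13 at the 95.9 percentile, within the central 95% of random lists, led by Hspa8 at 0.30 (0.27 to 0.33), a constitutive chaperone.

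Targets of p53 had a median of 0.15 (0.05 to 0.21) at the 97.7 percentile, with 7 of 12 members above the all-gene median. Cyclin G1, Ccng1, was at 0.39 (0.27 to 0.51), Phlda3 at 0.37 (0.12 to 0.61), Mdm2, the ubiquitin ligase of p53, at 0.22 and the pro-apoptotic gene Bax at 0.17 (0.12 to 0.23). Cdkn1a was at 0.05 (−0.12 to 0.21) and Bbc3 at 0.02 (−0.23 to 0.27), and 3 of the 12 members had ratios below 1. Apoptosis regulators had a median of −0.0017 (−0.12 to 0.11) at the 25 percentile, with Bcl2l1 at 0.24 (0.05 to 0.42).

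Growth factor feedback genes of receptor tyrosine kinases and MAPK had a median of −0.02 at the 6.29 percentile, with 11 of 15 members below the all-gene median. Spry2, an inhibitor of this signalling, was at −0.61 (−0.96 to −0.27) and the receptor gene Fgfr1 at −0.24, whereas Ccnd1, which encodes cyclin D1, was at 0.21 (0.05 to 0.37).

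Of the cell cycle lists, G2/M phase genes stood apart: 34 of 49 members lay below the all-gene median, and the list median of −0.03 (−0.06 to 0.02) was at the 0.09 percentile. With equal cluster shares in both libraries the median was 0.020. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, was at −0.28 (−0.39 to −0.17), the centromeric histone gene Cenpa at −0.18 and Cks2 at −0.15, but the mitotic kinase gene Nek2 was at 0.40 (0.16 to 0.65). S phase genes had a median of 0.05 at the 43.4 percentile, with 26 of 40 members at ratios above 1 and 14 below. Pola1, the catalytic subunit of DNA polymerase alpha, was at −0.64 (−0.86 to −0.42) and Wdr76 at −0.26 (−0.47 to −0.06). Slbp was at 0.16 (0.07 to 0.24) and Exo1 at 0.28 (0.07 to 0.50). Phase calls in thinned cells put 25.7% (22.4 to 29.2) of control and 22.7% (19.7 to 26.0) of Chd4 siRNA germ cell-like cells in G2M, a difference of −2.98 points (−7.63 to 1.67). Scored in each library alone, it was −7.97 points (−12.6 to −3.33). Phase calls are relative to the cells scored together, so in that setting the libraries are not on a common scale. With both libraries scored together, S phase calls were 32.6% and 33.5%, and G1 calls 41.7% and 43.7%.

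Cholesterol synthesis genes had a median of 0.15 (0.12 to 0.19), at the 99.8 percentile, with 14 of 16 members above the all-gene median. Cyp51 was at 0.33 (0.23 to 0.44), Sc5d at 0.35 and Idi1 at 0.21. Within the cluster led by Tmc3, which has the list member Dhcr7 among its leading genes, the median was 0.16 (0.14 to 0.26), at the 99.6 percentile. It was 0.11 (0.02 to 0.18) in that led by Nanos2 and 0.060 (−0.02 to 0.12) in that led by Esco2. These lay at the 94.8 and 46.8 percentiles, within the central 95% of random lists. Glycolysis genes had a median of −0.07 at the 1.93 percentile, yet their members split. Pkm was at 0.30, Ldha at 0.26 and Gapdh at 0.24, while the hexokinase gene Hk2 was at −0.35 (−0.51 to −0.20). Interferon response genes had a median of 0.11 (0.02 to 0.25) at the 83.0 percentile, with Bst2 at 0.21 and Ifi27 at 0.38, and a median of −0.00055 when all cells were used.

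Cytosolic ribosomal protein genes had a median of 0.01 but a mean of −0.08, and TMM and DESeq2 scaling, which lowered every gene by 0.05 and 0.03, gave medians of −0.04 and −0.02. A subset was far lower than the rest: Rps27rt, whose counts are uncertain because it is a near copy of Rps27, was at −0.81 (−0.88 to −0.75), Rps28 at −0.69 (−0.71 to −0.67), Rpl29 at −0.71, Rps29 at −0.64 and Rpl35 at −0.61. Histone genes had a median of 0.00 and a mean of −0.15, with Hist1h2ae at −0.83 (−1.24 to −0.43), Hist1h2bc at 0.38, H2afz at 0.14 and H3f3b at 0.13. The sign of some members turned with the cells used: Spry2 was at 0.29, Idi1 at −0.070, Tex101 at −0.026 and Hist1h2bc at −0.086 in G2M cells. In S phase cells Nupr1 was at −0.034, Phlda3 at −0.045 and Ube2c at 0.25. Ube2c was at 0.017 and Nek2 at −0.039 in G1 cells, and Ifi27 was at −0.0072 and Hist1h2bc at −0.016 in all deposited cells.

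**Figure D3:**
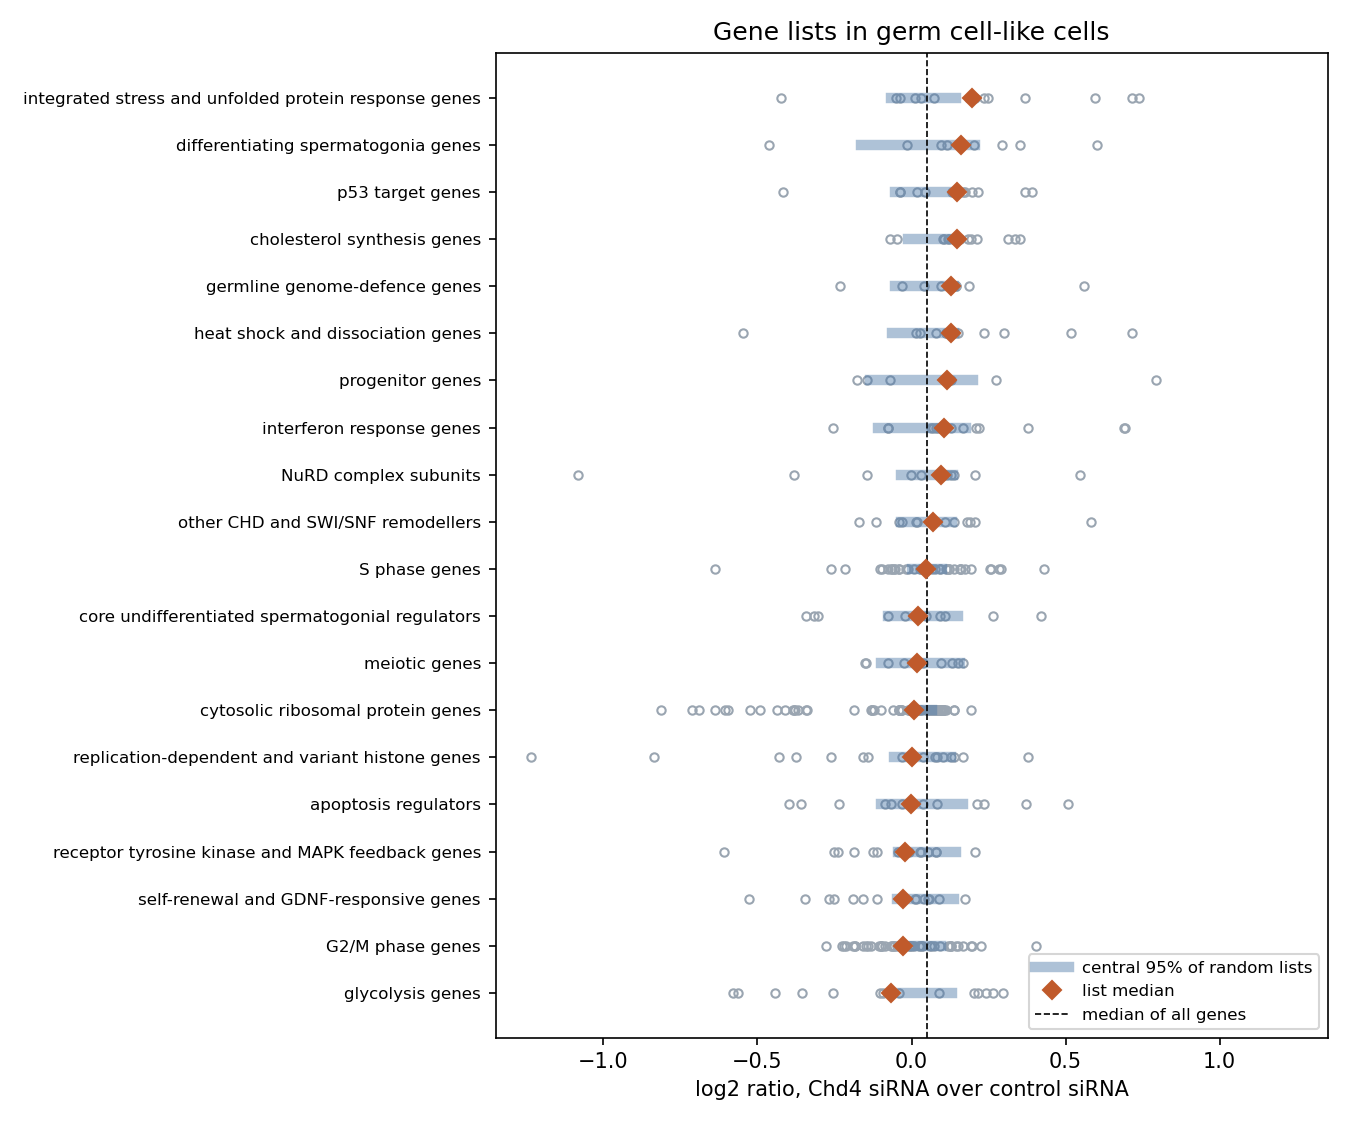
Log2 ratios of Chd4 siRNA over control siRNA in germ cell-like cells for members of each gene list (open circles), with the list median (diamond), the central 95% of medians of random lists matched on expression (bars) and the median of all genes (dashed line). Integrated stress genes have the highest median, 0.20, and glycolysis genes the lowest, −0.07.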

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

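Gene lists were compared between the cell classes, and 3 of them had medians on opposite sides of 0 with counting intervals that excluded 0 in both classes. The difference between the classes was not tested, since each class had 1 library per group, and comparing the classes and the checks for germ cell RNA were chosen after the values were seen. Cholesterol synthesis genes had a median log2 ratio of 0.15 (0.12 to 0.19) in germ cell-like cells and −0.36 (−0.47 to −0.20) in feeder fibroblast-like cells, where 12 of 16 members had ratios below 1. Interferon response genes had medians of 0.11 (0.02 to 0.25) and −0.50 (−0.61 to −0.28), with 11 of 14 feeder members at ratios below 1 but Cxcl10 at 2.04 (1.55 to 2.56) and Rsad2 at 1.09 (0.31 to 1.92) there. For S phase genes the medians were 0.05 (0.02 to 0.09) and −0.38 (−0.51 to −0.28). The list intervals treat genes as independent, and the share of cycling feeder cells was not computed. The median of all genes in germ cell-like cells was itself 0.05, and the S phase and interferon lists lay at the 43.4 and 83.0 percentiles of random lists there, within the central 95%. The germ cell S phase median was 0.0019 with TMM scaling, which lowered every gene by 0.05, and −0.011 with all deposited cells, where the interferon median was −0.00055. In the feeder class core spermatogonial regulators stood at −0.55 (−0.82 to −0.15) and self-renewal genes at −0.34 (−0.70 to −0.13), at the 3.46 and 4.11 percentiles, within the central 95% of random lists, and the intervals of meiotic, progenitor and genome-defence genes included 0. The summed germ cell markers stood at 87.3 and 79.6 CPM there, and 0 of the 20 and 6 called doublets were feeder cells. With the germ cell profile subtracted at the share of those markers, the feeder medians were −0.44 for cholesterol synthesis, −0.55 for interferon response and −0.41 for S phase genes. In feeder cells with under 150 CPM of germ cell markers they were −0.38, −0.62 and −0.20.

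Matrix rows without a gene name in the list held here carried a signal outside the comparisons, 12.1% of UMIs in the control library and 12.6% in the Chd4 siRNA library.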

How the results depend on the processing

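Over 41 main results, 288 alternative values lay within the counting interval (33 with the other sign, all where it included 0), 32 moved beyond it (2 with the other sign) and 6 reversed, with an interval that excluded 0. For single genes and feeder cell lists the numbers were 1177 (21), 135 (4) and 13. Except where named, the cause was not tested. The Chd4 log2 ratio stayed between −1.13 and −1.02, the latter in S cells. At most 20% of UMIs in unnamed rows, single or equally weighted clusters and the feeder checks were chosen after seeing the data. No paired analysis was possible because the replicates of each group were combined in 1 library. The mitochondrial filters and list were not run. Depth limits genes under 200 UMIs most.

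Of the 24 leading genes, 12 were also named with at least 1000 UMIs per gene, all that had so many, 15 with at least 50, 10 with all deposited cells, 11 of the 16 with enough UMIs in thinned cells, and 10 of 14, 10 of 13 and 7 of 14 within G1, S and G2M cells. The Chd4 detection difference was −9.13 points in unthinned cells and −31.4 points for at least 2 UMIs. Scored in each library alone, and so not on a common scale, the G2M difference was −7.97 points.

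TMM and DESeq2 scaling shifted every gene alike, by −0.046 and −0.032, so no gene or list changed its standing among the others. With TMM scaling the list medians were −0.074 for G2/M, 0.0019 for S phase, 0.10 for cholesterol synthesis, 0.082 for heat shock and −0.038 for ribosomal protein genes, the last reversed. DESeq2 scaling gave −0.060 for G2/M, 0.016 for S phase, 0.12 for cholesterol synthesis and −0.024, reversed, for ribosomal protein genes. With all deposited cells the medians were −0.085 for G2/M, 0.11 for cholesterol synthesis and 0.024 for ribosomal protein genes, and −0.011 for S phase and −0.00055 for interferon response genes, both reversed. Thinned cells gave −0.064 for G2/M, 0.018 for S phase and 0.022 for ribosomal protein genes. Means in place of medians gave −0.15 for histone genes and reversed NuRD subunits to −0.012 and ribosomal protein genes to −0.078. Stress response members with at least 200 UMIs had a median of 0.074. In the clusters led by Nanos2, Esco2 and Tmc3 the stress medians were 0.030, 0.31 and 0.036; cholesterol synthesis had 0.11 and 0.060 in the first 2. With equal cluster shares in both libraries G2/M had 0.020 and cholesterol synthesis 0.10.

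Single genes whose interval excluded 0 reversed in all deposited cells (Hist1h2bc −0.016, Ifi27 −0.0072), in G1 cells (Nek2 −0.039, Ube2c 0.017), in S cells (Nupr1 −0.034, Phlda3 −0.045, Sohlh1 −0.14, Ube2c 0.25, Xiap −0.028) and in G2M cells (Hist1h2bc −0.086, Idi1 −0.070, Spry2 0.29, Tex101 −0.026). With intervals that included 0, Isg15 moved to −0.20 in all deposited cells, Sycp2 to −0.15 in G1 cells, and Bcl2 to −2.12 and Sycp3 to −0.21 in S cells, each to the other sign.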

Other observations

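Of the tests below, the count of stretches of 19 bases was the one set out before its result was seen; the tests of shared stretches of 50 bases, of the 7-base word, of short mRNAs and of germ cell RNA in feeder cells were chosen after related values had been seen.

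In the feeder fibroblast-like cells, which also had less Chd4, integrated stress genes had a median log2 ratio of 0.37 (0.22 to 0.53), above all 10000 random lists, with Atf3 at 1.92 (1.20 to 2.70) and Trib3 at 1.02. Heat shock genes had a median of 0.31, with Junb at 0.62 and Hspa8 at 0.42. G2/M genes had a median of −0.43 (−0.50 to −0.30), below all random lists, with 42 of 49 members at ratios below 1, Cenpa at −0.72 and Ube2c at −0.51. Random lists were drawn gene by gene, so these ranks do not allow for genes that vary together across cells. The share of cycling cells among the 79 and 92 feeder cells was not computed. Fewer such cells therefore cannot be told apart from a lower level per cell. Of the interferon response genes, Bst2 was at −0.52 and Oasl2 at −0.72, but Cxcl10 was at 2.04 (1.55 to 2.56), from 42 and 199 UMIs, and Rsad2 at 1.09 (0.31 to 1.92). Core spermatogonial regulators had a median of −0.55 (−0.82 to −0.15) over 5 members, self-renewal genes −0.34 (−0.70 to −0.13) over 6, meiotic genes −0.63 (−1.19 to 0.02) over 4, genome-defence genes −0.31 (−0.56 to 0.21) over 6 and progenitor genes −0.20 (−0.73 to 0.13) over 5, all within the central 95% of random lists, at the 3.46, 4.11, 6.32, 19.7 and 32.2 percentiles. The 12 germ cell markers summed to 87.3 and 79.6 CPM in feeder cells, a log2 ratio of −0.13 (−0.38 to 0.11), and 3.97% and 3.34% of their level in germ cell-like cells. Scrublet called 20 and 6 cells doublets, 0 of them feeder cells. With the germ cell profile subtracted at these shares the medians were −0.44 for G2/M and 0.38 for integrated stress genes. Among the 66 and 81 feeder cells with under 150 CPM of germ cell markers they were −0.32 and 0.24, and 0.16 for heat shock genes.

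Chd4 UMIs were spread unevenly over the germ cell-like cells of the Chd4 siRNA library. In thinned cells their variance was 2.34 times the mean, higher than for 98.1% of 316 genes of like mean, against 2.02 times and 90.3% of 124 genes in the control library. Cells without a Chd4 UMI were 18.8%, where the genes of like mean had a median of 13.2% and a Poisson spread would give 9.57%, and 90.5% of those genes had fewer such cells. In the control library cells without one were 2.56% against 2.11% for genes of like mean, of which 60.5% had fewer.

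Chd3 was lower together with Chd4, at −0.38 in germ cell-like cells and −2.12 (−2.53 to −1.73) in feeder fibroblast-like cells, from 253 and 67 UMIs. Chd4 reads counted for Chd3 are argued against, since annotated Chd3 and Chd4 transcripts shared 0 stretches of 50 bases. An siRNA with a full match in Chd3 may be a source, as 68 stretches of 19 bases were shared, but such sharing says little, since 51 were shared with Chd5, which was at 0.55 (0.17 to 0.93), and the siRNA sequences were not used here, so this cannot be told apart from a lower Chd3 level that follows from less Chd4. The latter was not tested.

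Genes with the word TCGAGAC in the 3′ UTR differed from other genes by −0.06 in mean log2 ratio after adjustment for length and base content (218 genes in germ cell-like cells), the lowest rank of 14942 words. It ranked 3 of 13802 words in feeder fibroblast-like cells, at −0.08. Silencing of further genes through the seed of the Chd4 siRNA is thus a candidate explanation, found and tested on the same libraries. That the word occurs in Chd4 adds little, since 4 of the 10 lowest and 4 of the 10 highest words do. Of 7 leading lower genes searched only Jund carries it, and Jund stood at 0.26 (−0.01 to 0.53) in the feeder class. The 3′ UTR of Chd3 lacks the word. Base composition of the word could not be decided by rank. In the feeder class the word had rank 1 of 121 words with the same bases and a CG pair. This rank adds little, since it already ranked 3 of all words there and both classes share their libraries. The median of those 121 words was 0.01, so words of this composition were not low as a group. Counted over genes with the word only in the coding part, TCGAGAC ranked at the 49.8 and 71.9 percentiles of coding words in the germ and feeder classes. Neither check can tell an siRNA seed from a longer stretch of 3′ UTR sequence that holds the word. Of the 10 lowest words in germ cell-like cells 2 were in the lowest 1% of the feeder class. The highest germ cell word, ATGGGAG, ranked 13792 of 13802 there, so agreement between the classes was not particular to TCGAGAC. Effects shared by whole libraries thus stay open, and a response to less Chd4 was not tested.

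Short ribosomal protein mRNAs were lower in the Chd4 siRNA library, with a median of −0.34 for 17 genes of at most 600 bases against 0.05 for 62 longer ones in germ cell-like cells. A response of the germ cells alone is argued against, since the median of the 17 genes was −0.29 in feeder fibroblast-like cells. Less recovery of short cDNA in the Chd4 siRNA library may account for it: 74 other genes of at most 600 bases had a median of −0.17 in germ cell-like cells, and 48 had −0.19 in feeder cells, both below the central 95% of random sets. A response to Chd4 siRNA in both cell classes remains open and was not tested.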
